A study of Mus musculus with 4 samples.

How the data were processed

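RNA from the trachea of mouse embryos at embryonic day 16 was hybridised to 4 Affymetrix arrays, 2 of wild type and 2 of an a1H knockout. Per the labels' protocols, total RNA was extracted with Trizol, 50 ng was converted to cDNA by SPIA amplification with the Ovation Pico system, and 3.75 µg of cDNA was labelled with biotin. The deposited values are intensity values on a linear scale, 1 signal per probe set and array, made with MAS5 per the submitters' processing notes. The MAS5 version and settings are not given in the sources used here. In the deposited intensities the mean after trimming 2% from each end was 1500 on every array, so the values looked scaled per array to a common target. Medians and upper percentiles still differed between arrays, so they were not quantile normalised. MAS5 gives noisy values for dim probe sets, and amplification of small RNA amounts favours 3' ends. Both can change measured differences. No detection calls were used here.

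Groups and replicate numbers were taken from sample titles. Probe sets were paired with genes through a table of platform annotation: 34945 had exactly 1 gene, 932 had several and 9160 had none listed, and 64 control probe sets were left out. Symbols of 34741 probe sets were updated through gene identifiers in a RefSeq table of the assembly GRCm38.p6, which was used only for names and gene order. For each of 18193 genes the probe set with the highest mean log2 value over all 4 arrays was kept, and genes were tested where this mean was at or above the median of all non-control probe sets, a signal of 397. This left 11694 genes.

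Signals were tested as log2(signal + 16) with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend, genotype as the only term and all 4 arrays in the fit. Fold changes are on the log2(signal + 16) scale, which understates differences of dim genes. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Signals are given as mean ± SD over 2 arrays, and SEs are the moderated ones of the fit. Gene lists, 14 of pathways and 20 of cell types, were fixed before the data were examined and were tested with camera with a preset correlation of 0.01 where at least 5 members were measured. Adjustment was over the 33 lists tested, and camera with an estimated correlation and fry were run beside it. The direction of a list in a test is the direction that camera gives, and its median can have the other sign where differences are small. The 50 tested genes on each side of Cacna1h in chromosomal order were compared with all other genes by a two-sided Fisher's exact test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

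Named genes follow a rule written before the data were examined. They are Cacna1h, then in each direction the 12 genes with the largest change among those past the threshold, with places filled by the smallest unadjusted p among genes at least 2-fold different whose groups do not overlap. Further named genes are Sox9, Col2a1, Acan, Col9a1, Matn1, Comp, Nfatc1, Rcan1, Cacna1g, Cacna1c and Acta2 whatever their values, and up to 4 members of each list with the smallest unadjusted p. Genes of other organs that fall outside this rule, such as Tpbpa, Prl8a9, Myh6 and Flg, were chosen after their values were seen. So were 5 further marker lists, of placenta, liver and yolk sac, skin and hair, salivary gland and thymic epithelium.

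Scripts were tested on simulated data before use. In 10 runs over 11694 genes with 200 changed genes each, made for the comparison of knockout with wild type, SDs drawn from the fitted prior gave a recovery of 14.0% of 2-fold, 82.4% of 4-fold and 97.9% of 8-fold changes, and 6.24% of calls were false. With the moderated SDs of the real fit as true values the recovery was 49.0%, 98.8% and 99.8%, and 9.05% of calls were false, above the nominal 5%. With independent genes, a simulated shift of 0.3 in the 27 genes of the cartilage list was called in 10 of 10 runs with the preset correlation and in 0 of 10 with an estimated one. Over these 10 runs of 33 lists before the shift, 1 and 4 list calls were made with the preset correlation under the 2 sources of SDs. The real cartilage list had an estimated correlation of 0.34, and lists of correlated genes were not simulated, so these runs do not show how often the preset test calls such a list by chance.

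Alternatives were the pseudocount (1 and 64), no filter and a filter at the 75th percentile, quantile normalisation, centring of arrays, no intensity trend, array weights, the mean of all probe sets of a gene, the replicate number as a block, each array left out in turn, and 25 genes in place of 50 beside Cacna1h. Combinations of the block with quantile normalisation and with an estimated correlation were added after the data were seen.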

Results

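Gene expression was measured in the trachea of mouse embryos at embryonic day 16 on a C57BL/6 background, with 1 Affymetrix array of 45101 probe sets per sample. The labels give 2 wild-type samples and 2 samples of an a1H knockout, numbered 1 and 2 in each genotype. a1H is taken here as the alpha-1H subunit of the Cav3.2 T-type calcium channel, a voltage-gated channel encoded by Cacna1h. The comparison asks which transcripts differ between knockout and wild-type trachea, and the study is known to concern the cartilage of the tracheal wall. The deposited values were MAS5 signals on a linear scale, and the array medians were 459 and 416 in wild type and 426 and 320 in the labelled knockout. Nothing in the labels says whether samples came from separate embryos, litters or pools, so p-values measure the spread between these samples, which may be technical. Only 2 arrays per group limit the precision, and an exact two-sided permutation test of 2 against 2 cannot give a p below 0.333.

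Technical measures also differed among the arrays. The geometric mean of the 9 spiked hybridisation control probe sets was 6361 and 6258 on the replicate 1 arrays and 14756 and 18565 on the replicate 2 arrays, so arrays of the same number were alike in this measure. The labels do not say whether the numbers mark a batch, and differences within each replicate number are given beside pooled ones. The actin 3' to 5' signal ratio, a sign of RNA length, was 1.69 and 1.66 in wild type and 1.90 and 1.97 in the labelled knockout. The same ratio for Gapdh was 1.26 and 1.40 in wild type and 1.36 and 1.61 in the labelled knockout.

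Cacna1h, the gene the labels name as knocked out, was not lower on the labelled knockout arrays. Its brighter probe set, 1422710_a_at, read 630 and 538 in wild type and 981 and 631 in the labelled knockout, or 584 ± 64.5 against 806 ± 248 (SD, n = 2 per group). The log2 difference, labelled knockout minus wild type, was 0.43 with an SE of 0.32 and an adjusted p of 0.875 in the limma fit. Its other probe set, 1427607_at, was dim on all 4 arrays at 99.7, 28.1, 79.2 and 60.3. A probe set outside the deleted part of a gene checks nothing, and neither the deleted part nor the probe positions were known here, so the genotype labels could not be checked and directions below rest on them.

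No gene passed the test between labelled knockout and wild type. Of 11694 genes tested with limma, 0 had a Benjamini-Hochberg adjusted p under 0.05, and the smallest was 0.875. At an unadjusted p under 0.05 there were 536 genes, 331 higher and 205 lower in the labelled knockout, where chance alone gives 585. The groups did not overlap for 4217 genes, or 36.1% of those tested, against 33.3% by chance. The median SE of a log2 difference was 0.24 and the median half-width of the 95% interval 0.57, before adjustment for the number of genes tested. Larger differences could be missed too. Of simulated 2-fold changes, 14% were recovered with SDs from the fitted prior and 49% with the moderated SDs. Among all 22519 probe sets above the median level, including 2941 not paired with exactly 1 gene, 0 passed. The count depended on single arrays: 492 genes passed without labelled knockout replicate 1, 104 without labelled knockout replicate 2 and 1, the salivary gland gene Smgc, without wild-type replicate 2.

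The genes with the smallest unadjusted p among those at least 2-fold different and without overlap are given as values, since none passed and each had an adjusted p of 0.875. Of the 12 higher in the labelled knockout, Ptgds, which encodes lipocalin-type prostaglandin D synthase, read 1347 ± 316 in wild type and 6543 ± 2963 in the labelled knockout (SD, n = 2 each), a log2 difference of 2.21 with an SE of 0.33. Pax1, a transcription factor of the sclerotome and pharyngeal pouches, read 891 ± 418 and 3029 ± 46.1 (SD, n = 2), a log2 difference of 1.83. Several of the others are known from the thymus, namely Psmb11, Prss16, Ccl25, Thy1 and the T-cell receptor segment Trgv4. Psmb11, the proteasome subunit of thymic cortical epithelium, had a log2 difference of 3.26 between the replicate 1 arrays and 0.96 between the replicate 2 arrays. The remaining genes were Tarbp2, Tmem242, Rec114, Fgf14 and Bpifa1, a secreted airway protein at 887 ± 149 and 3018 ± 1917 (SD, n = 2). Tarbp2 had a log2 difference of 1.78 on probe set 1438952_x_at but 0.47 on 1423616_at, and x_at probe sets can bind more than 1 transcript.

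Among the 12 lower genes, Ucma, which encodes a secreted cartilage matrix protein, read 7681 ± 387 in wild type and 3158 ± 640 in the labelled knockout (SD, n = 2 each), a log2 difference of -1.29 with an SE of 0.20. Its other probe set gave -1.30. The myosin heavy chain genes of fast skeletal muscle, Myh4 and Myh1, had log2 differences of -2.60 and -2.12, and the antisense transcript Myhas of the same locus had -1.89. Transcripts of these myosins are similar in sequence, so their probe sets may not be independent. Tmem212 read 2336 ± 211 and 894 ± 20.2 (SD, n = 2), and Scg5, a secretory granule chaperone of neuroendocrine cells, read 2659 ± 7.83 and 1291 ± 174 (SD, n = 2). Pde5a, the cyclic GMP phosphodiesterase of smooth muscle, had a log2 difference of -1.08 on its brightest probe set and -0.31 and -0.71 on 2 others, and Gp2, Fgfbp3, AU040972 and G530011O06Rik had -1.65, -1.34, -1.03 and -2.20. Mid1 had -2.02 on its brightest probe set and -0.73 on a dimmer one, and 0.80 on another that read at most 59.3.

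Cartilage matrix genes were lower as a list in the labelled knockout, by a small amount that came from the replicate 1 arrays. Of 27 measured members 19 were lower, 12 of them within both replicate numbers, and the median log2 difference was -0.18, with -0.36 between the replicate 1 arrays and 0.02 between the replicate 2 arrays. The camera test with a preset correlation gave an adjusted p of 0.00044, and with an estimated correlation the adjusted p was 0.839. With simulated independent genes the estimated form called a shift of 0.3 in this list in 0 of 10 runs. It therefore cannot decide here. Without labelled knockout replicate 1 the median was 0.02 and the adjusted p 0.776, and the median was -0.34 without labelled knockout replicate 2 and -0.11 without wild-type replicate 1. No member passed over all genes tested, and 1 member, Ucma, passed when adjusted over the list alone. Col11a2, a chain of cartilage collagen, read 2051 ± 239 in wild type and 1392 ± 162 in the labelled knockout (SD, n = 2), a log2 difference of -0.55. Snorc, a chondrocyte membrane proteoglycan, had -0.70, and Col27a1 had -0.35. Col2a1, the main cartilage collagen, read 19882 ± 6242 and 21166 ± 9273 (SD, n = 2), and Acan, the large aggregating proteoglycan, read 16773 ± 3124 and 14503 ± 3388 (SD, n = 2), with overlapping groups in both. Col9a1, a fibril-associated collagen of cartilage, read 22674 ± 1539 and 18489 ± 2215 (SD, n = 2) without overlap, a log2 difference of -0.30 with an SE of 0.26. Those of Matn1 and Comp were both 0.11, with SEs of 0.24 and 0.29.

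**Figure D1:**
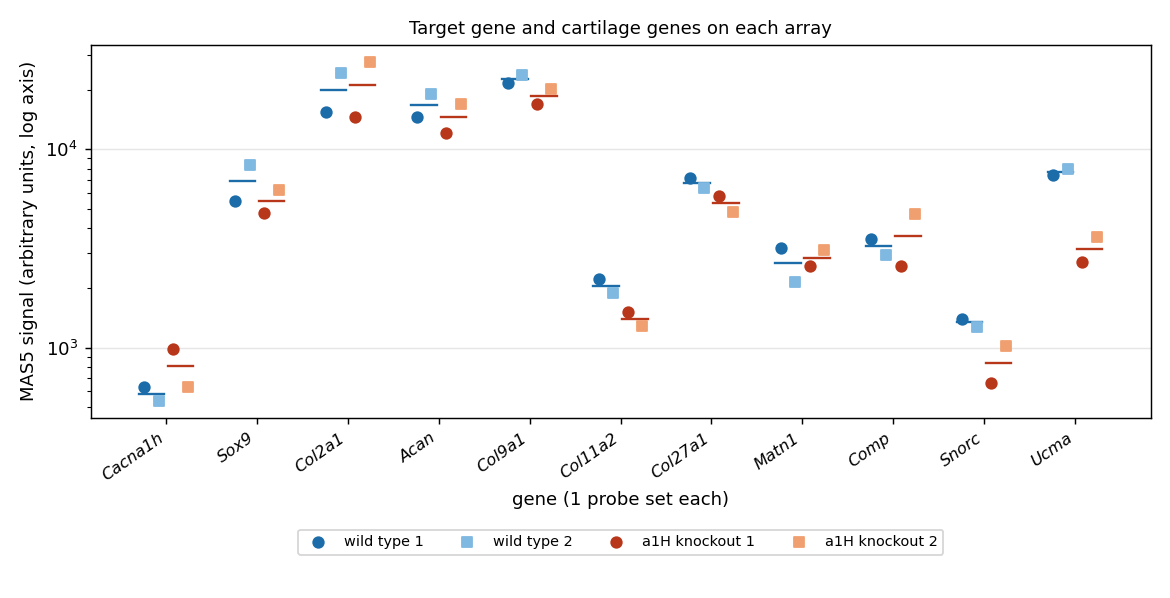
MAS5 signal (log axis) of Cacna1h, Sox9 and 9 cartilage matrix genes on each of the 4 arrays, with points for arrays (circles replicate 1, squares replicate 2) and short lines for the means of 2 arrays. Ucma lies between 7407 and 7954 in wild type and between 2705 and 3610 in the labelled knockout, whereas the groups overlap for Col2a1.

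Regulators of cartilage formation were lower in 15 of 22 measured members, with a median log2 difference of -0.20 and an adjusted camera p of 0.083, which did not pass. Sox9, the transcription factor required for chondrocyte identity, read 6920 ± 2018 and 5492 ± 1042 on its brightest probe set (SD, n = 2), a log2 difference of -0.31 with an SE of 0.25. A second Sox9 probe set, 1424950_at, read 3363 and 2994 in wild type and 2354 and 947 in the labelled knockout, a log2 difference of -1.08. Fgfr3 and Bmpr1b, receptors that act in growing cartilage, had log2 differences of -0.49 and -0.36. Only Pax1, a factor of the pharyngeal pouches as well as the sclerotome, passed when adjusted over the list alone, in the opposite direction. Whether its difference comes from cartilage cells was not tested. Genes of hypertrophic cartilage and bone did not pass as a list (adjusted p = 0.11), with 5 of 7 members higher and medians of 0.04 and 0.68 within replicate numbers 1 and 2. Mmp9, a protease of cartilage resorption, had a log2 difference of 0.86.

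Genes of calcium signalling did not pass the test as lists. The calcineurin and NFAT list had 11 of 20 members higher, a median log2 difference of 0.01 and an adjusted camera p of 0.924. Nfatc1, a calcineurin-regulated transcription factor, read 1780 ± 29.6 and 1876 ± 116 (SD, n = 2), and Rcan1, a target and inhibitor of calcineurin, read 3126 ± 595 and 3452 ± 1006 (SD, n = 2). Camk2g, a calmodulin-dependent kinase subunit, had a log2 difference of 0.64. Voltage-gated calcium channel subunits had 8 of 14 members higher, a median of 0.09 and an adjusted p of 0.901. Cacna1g, another T-type channel gene, read 609 ± 116 and 841 ± 49.2 (SD, n = 2), a log2 difference of 0.47 with an SE of 0.28, and Cacna1c, the L-type channel gene, had 0.16 with an SE of 0.38. The calcium stores and pumps list had a median of -0.01 and an adjusted p of 0.901, with medians of 0.20 and -0.25 within replicate numbers 1 and 2, and Stim1, the sensor of calcium stores, had a log2 difference of -0.87.

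Proliferation genes were higher in the labelled knockout in all 27 measured members, 23 of them within both replicate numbers. The median log2 difference was 0.33, with 0.28 and 0.40 within replicate numbers 1 and 2, and the adjusted camera p was 7.2e-06. With an estimated correlation the adjusted p was 0.652. Bub1b, a spindle checkpoint kinase, read 2373 ± 466 and 3829 ± 517 (SD, n = 2), a log2 difference of 0.69. Aurka, Kif20a and Ccnb2, which act in mitosis, had 0.53, 0.52 and 0.45. No member passed over all genes or when adjusted over the list alone. Other lists also differed on these arrays, with the T-cell list 2.80 higher between the replicate 1 arrays and placental transcripts on labelled knockout replicate 2, as given below. Oxidative phosphorylation genes were higher in 24 of 25 members, with a median of 0.19, values of 0.23 and 0.19 within the replicate numbers and an adjusted p of 0.0066, which was 0.873 with an estimated correlation. Its call was lost without wild-type replicate 1 (median 0.04) and without labelled knockout replicate 2 (0.02), while the median was 0.42 without wild-type replicate 2 and 0.34 without labelled knockout replicate 1. Cyc1 and Ndufv1, subunits of the respiratory chain, had log2 differences of 0.45 and 0.42.

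Targets of WNT, hedgehog, FGF and TGF-beta signalling were lower in 17 of 22 members, with a median log2 difference of -0.18, -0.25 and -0.09 within the replicate numbers, and an adjusted camera p of 0.0092. With an estimated correlation the adjusted p was 0.652. The call was lost without wild-type replicate 1 (median -0.14) or labelled knockout replicate 1 (-0.10), with no filter on dim probe sets and with the mean of all probe sets of a gene. Wif1, a secreted WNT inhibitor, Hhip, a hedgehog-binding protein, and Foxf1, a hedgehog-responsive transcription factor of the airway wall, had log2 differences of -0.63, -0.55 and -0.50. The remaining pathway lists did not pass. Their medians were 0.12 for glycolysis and hypoxia (adjusted p = 0.244), -0.02 for immediate early genes (0.378) and 0.08 for stress and unfolded protein response (0.901). They were -0.12 for interferon response (0.752) and 0.14 for ribosomal proteins (0.602). Of the glycolysis and hypoxia genes 18 of 20 were higher, among them Hk1, Pfkl and Pdk1, enzymes of glucose use, with log2 differences of 0.50, 0.40 and 0.37, whereas Vegfa, the endothelial growth factor, had -0.70. Asns, asparagine synthetase of the stress list, had a log2 difference of 0.64.

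Genes of multiciliated and of secretory airway epithelium were lower in the labelled knockout as lists by the camera test. Of 21 measured genes of multiciliated cells, 16 were lower, with a median log2 difference of -0.21, values of -0.23 and -0.28 within the replicate numbers and an adjusted p of 0.017, which was 0.652 with an estimated correlation. Rsph4a, a radial spoke protein, read 1314 ± 118 and 758 ± 22.1 (SD, n = 2), a log2 difference of -0.78, and Ccdc39 and Ccdc153 had -0.74 and -0.71, whereas Dnah11, an axonemal dynein, had 0.73. Secretory and gland cell genes were lower in 14 of 17 members, with a median of -0.38, values of -0.05 and -0.44 within the replicate numbers and an adjusted p of 0.0016, which was 0.839 with an estimated correlation. On the array, 14 of 18 genes of this list were highest on wild-type replicate 2, which also held salivary gland transcripts such as Smgc, at 28112 against 3.74 on wild-type replicate 1. Tff2, a trefoil peptide, read 1060 ± 144 and 412 ± 99.0 (SD, n = 2). Scgb1a1, the club cell secretoglobin, read 6483 and 17814 in wild type and 5542 and 5817 in the labelled knockout, whereas Bpifa1, named above, had a log2 difference of 1.60. Leaving out wild-type replicate 2 ended both calls, with medians of -0.15 and -0.19, and the secretory median was -0.61 without wild-type replicate 1. The multiciliated call also ended without labelled knockout replicate 1 (median -0.14), above the 75th percentile of level and with the mean of all probe sets of a gene. Basal and general epithelium had a median of -0.09 and an adjusted p of 0.078, with Sox2, a transcription factor of the foregut, at -0.60.

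The mesenchymal wall lists did not pass in the main fit, with genotype as the only term. With a block for the replicate number, airway smooth muscle (adjusted p = 0.039) and fibroblasts and perichondrium (0.011) passed camera with the preset correlation. With the block and an estimated correlation these were 0.914 and 0.795. In the main fit, airway smooth muscle genes had a median log2 difference of -0.11 and an adjusted p of 0.062, with medians of 0.19 and -0.66 within replicate numbers 1 and 2. Acta2, smooth muscle actin, read 20956 ± 5962 and 19340 ± 1738 (SD, n = 2), while Actg2, the gamma form, had a log2 difference of -0.71. Fibroblast and perichondrium genes were lower in 18 of 24 members, with a median of -0.11 and an adjusted p of 0.064, and Col12a1, a fibril-associated collagen, read 8318 ± 685 and 5613 ± 407 (SD, n = 2). The endothelium had a median of -0.10 (adjusted p = 0.149), neurons -0.09 (0.378) and Schwann and glial cells -0.04 (0.895). Ret, a receptor of enteric and sympathetic neurons, had a log2 difference of -0.60, Sox10, a transcription factor of glia, had 0.96, and Mmrn1, a lymphatic marker, had -0.82. Macrophage genes had a median of -0.05 (0.602), and mast cells and granulocytes had 0.15 (0.754).

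Markers of organs beside the trachea were present on the arrays and differed between samples of the same genotype. All 8 measured thymocyte and T-cell genes were higher in the labelled knockout, with a median log2 difference of 1.33. The adjusted camera p was 4.6e-05 with the preset correlation and 0.830 with an estimated one. That estimate was 0.98 for this list, so its genes were far from independent and the preset p overstates the evidence. The median was 2.80 between the replicate 1 arrays and -0.14 between the replicate 2 arrays, and the wild-type arrays themselves differed by 1.40. The median was 0.61 without wild-type replicate 1, 2.01 without wild-type replicate 2 and 0.71 without labelled knockout replicate 1. Wild-type replicate 2 with labelled knockout replicate 1 against the rest gave this list a smaller adjusted camera p than the genotype. It was 1.1e-20 with the preset correlation. Cd3d, a T-cell receptor subunit, read 485 and 1884 in wild type and 4760 and 1982 in the labelled knockout. No member passed over all genes, and 2 passed when adjusted over the list alone. Psmb11, Prss16 and Ccl25, named above, belong to the same organ.

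Thyroid genes were lower in all 5 measured members, with a median log2 difference of -0.49, values of -0.29 and -0.44 within the replicate numbers and an adjusted p of 0.0020, or 0.652 with an estimated correlation. Without labelled knockout replicate 2 the thyroid median was -0.31. Tg, thyroglobulin, read 24128 ± 5319 and 17134 ± 2946 (SD, n = 2), and Hhex had a log2 difference of -0.55. Lung distal epithelium genes were lower in 5 of 8 members, with a median of -0.21, values of -0.43 and -0.28 within the replicate numbers and an adjusted p of 0.016, or 0.652 with an estimated correlation. Napsa, Ager and Sftpc, markers of alveolar epithelium, had log2 differences of -1.16, -1.02 and -2.16, and Sftpc read 732 and 3967 in wild type and 320 and 426 in the labelled knockout, a difference of -0.96 without wild-type replicate 2 and -3.37 without wild-type replicate 1. Of this list, 3 members passed when adjusted over the list alone. The lung median was -0.06 without wild-type replicate 1, -0.36 without wild-type replicate 2 and -0.37 without labelled knockout replicate 1, and the call was lost above the 75th percentile of level (median 0.17). Erythroid genes were higher in all 7 members, with a median of 0.36, values of 0.17 and 0.57 within the replicate numbers and an adjusted p of 0.0092, or 0.652 with an estimated correlation. Hbb-y, an embryonic globin, read 9863, 4603, 7146 and 19305 on wild-type arrays 1 and 2 and labelled knockout arrays 1 and 2. The erythroid call was lost without wild-type replicate 2 (median 0.28) or labelled knockout replicate 2 (0.30), the array that also held placental transcripts.

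Cardiac muscle genes had a median log2 difference of 0.14 and an adjusted p of 0.712, with 0.89 between the replicate 1 arrays and -0.50 between the replicate 2 arrays. Myh6, the atrial myosin, read 9554 and 3202 in wild type and 16214 and 294 in the labelled knockout. Skeletal muscle genes had a median of 0.15 and an adjusted p of 0.149, with Tnni1, slow troponin I, at 6957 ± 858 and 11513 ± 684 (SD, n = 2). Medians were -0.13 for squamous epithelium (adjusted p = 0.486), -0.17 for parathyroid and C cells (0.104) and 0.13 for adipocytes (0.901). Of the sex-linked list, 4 members were measured, too few for the test. Xist read 15029 ± 219 and 13385 ± 290 (SD, n = 2), and the Y-linked Eif2s3y read 6391 ± 1098 and 5778 ± 88.9 (SD, n = 2), so Xist, known from females, and the Y-linked Eif2s3y were bright on each array. These values argue against RNA of a single embryo alone in each sample. Pooled embryos and RNA of other animals cannot be told apart here. The Y-linked Kdm5d and Uty had log2 differences of -0.62 and -0.82, and Uty read 811 and 701 in wild type and 606 and 288 in the labelled knockout. Placental transcripts appeared on the labelled knockout replicate 2 array, where Tpbpa, a trophoblast gene, read 37380 against 126, 374 and 136 on wild-type replicates 1 and 2 and labelled knockout replicate 1. The same array takes part in every list above.

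**Figure D2:**
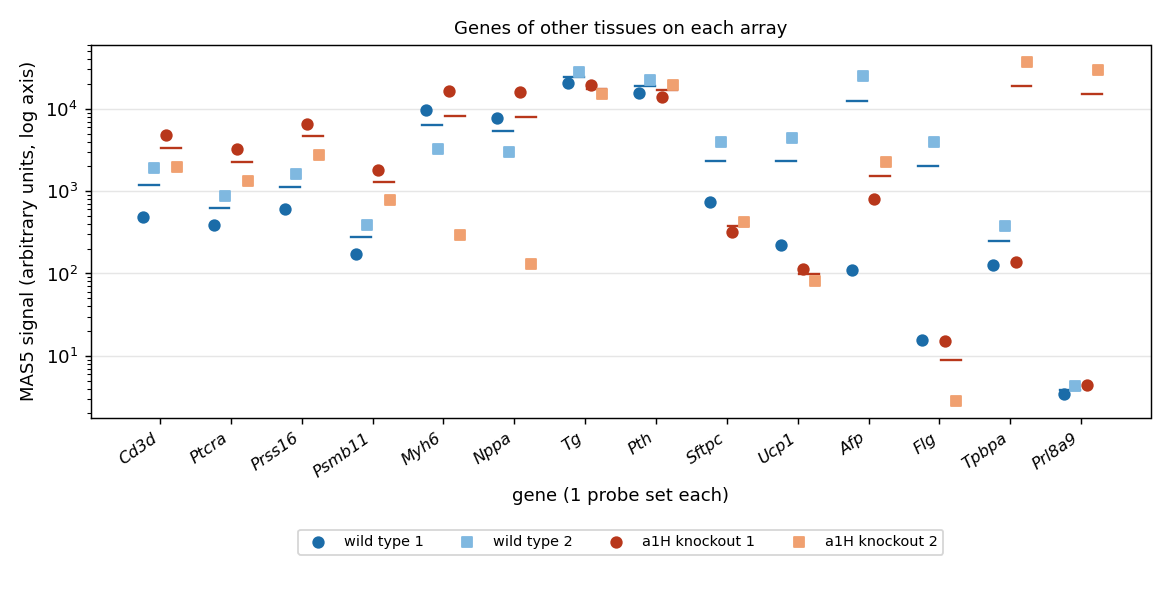
MAS5 signal (log axis) of 14 genes known from thymus, heart, thyroid, parathyroid, lung, brown fat, liver, skin and placenta on each of the 4 arrays, with points for arrays (circles replicate 1, squares replicate 2) and short lines for the means of 2 arrays. Prl8a9 reads 29880 on the labelled knockout replicate 2 array and at most 4.43 on the other arrays, and Flg reads 4001 on the wild-type replicate 2 array.

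Over the 33 lists tested, 10 passed camera with a preset correlation of 0.01, 4 higher and 6 lower in the labelled knockout, and 8 of these 10 had medians of the same sign within both replicate numbers. With quantile normalisation 14 lists passed, 4 higher and 10 lower, and 18 passed without wild-type replicate 1 or without labelled knockout replicate 2, 4 higher and 14 lower in each case. With an estimated correlation none of the 33 passed, and the smallest adjusted p was 0.652. That form called the simulated shift of 0.3 in 0 of 10 runs, so a list that does not pass it is left undecided. Proliferation did not pass it even at an estimated correlation of 0.016, near the preset 0.01. Its unadjusted camera p was 0.040 there and 2.2e-07 with the preset value, so correlation within the list does not by itself account for the larger p. Some other lists that passed with the preset value had higher estimates, at 0.98 for T cells, 0.42 for oxidative phosphorylation, 0.37 for secretory cells and 0.34 for cartilage. The median and the camera direction differed in sign for the calcineurin and NFAT, calcium channel, stress, mast cell and Schwann cell lists, and the median and the mean for the stress, interferon, cardiac, mast cell and Schwann cell lists, none of which passed. Rotation tests with fry, which ask whether the genes of a list move one way on balance, gave 0 lists, with a smallest adjusted p of 0.432.

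**Figure D3:**
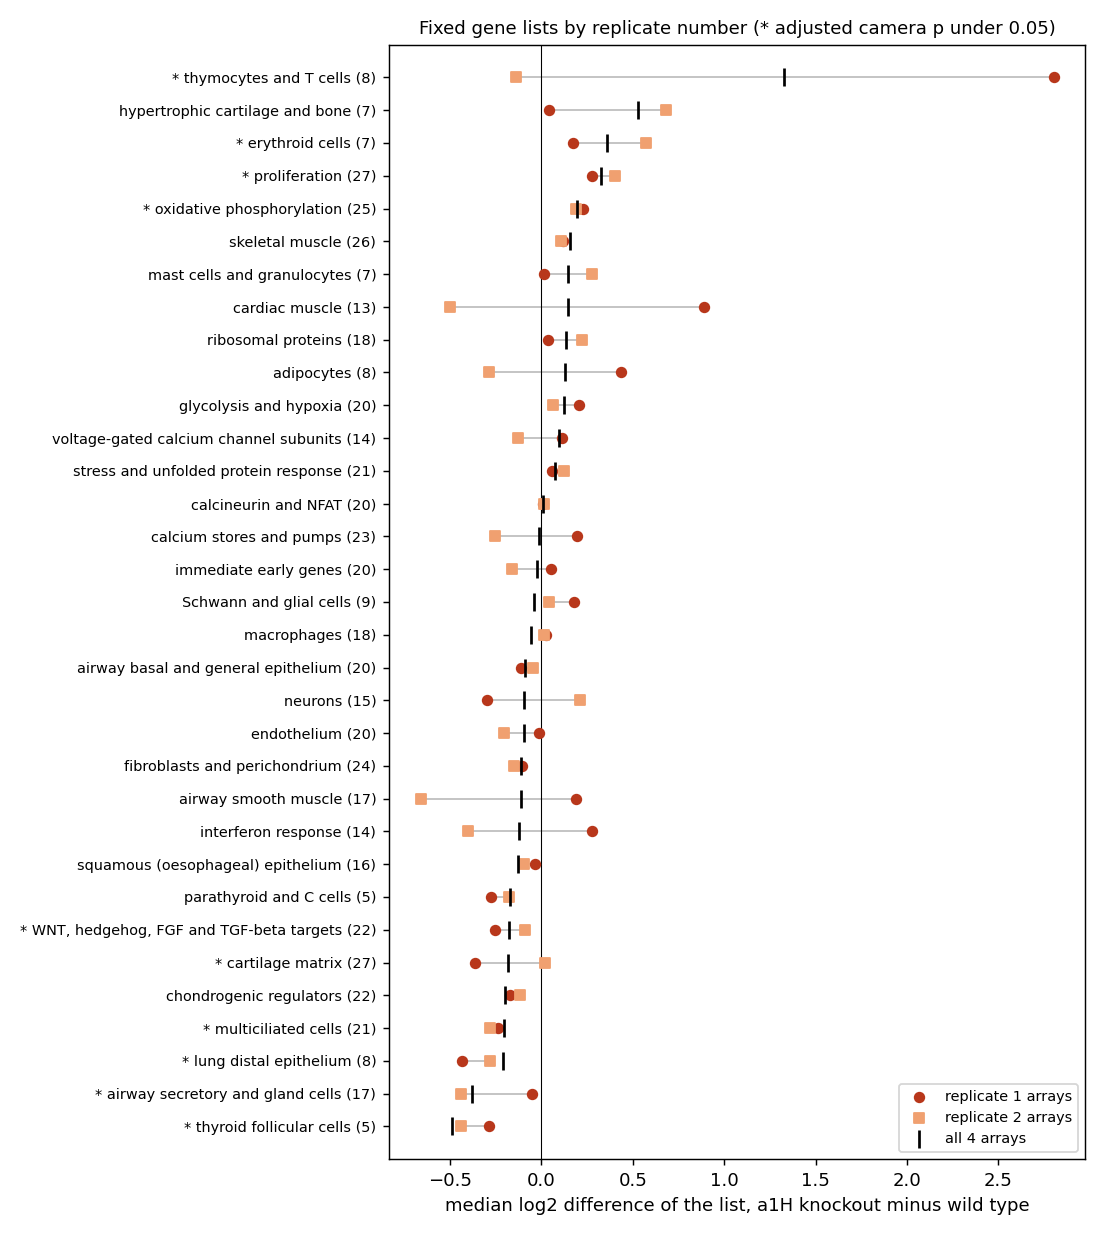
Median log2 difference, labelled knockout minus wild type, of each of the 33 tested gene lists, with the number of measured genes in brackets. Circles show the replicate 1 arrays, squares the replicate 2 arrays and vertical ticks all 4 arrays. Thymocytes and T cells lie at 2.80 and -0.14, whereas proliferation genes lie at 0.28 and 0.40.

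Genes beside Cacna1h on chromosome 17 did not stand out from the rest of the genome. A knockout made in stem cells of another strain can keep that strain's flanking chromosome. This comparison would show such a stretch only where it changed expression, and with no gene passing in the fit it cannot exclude one. Among the 50 tested genes on each side, 5 of 100 had an unadjusted p under 0.05, against 531 of 11594 elsewhere (4.58%), an odds ratio of 1.10 with a two-sided Fisher's exact p of 0.808. Those 5 were Nubp2, Flywch1, Capn15 and Ccnf, with log2 differences of 0.70, 0.55, 0.40 and 0.61, and Dnase1l2 with -0.68, named after their values were seen. None of the 100 passed after adjustment. For the group the median log2 difference was 0.14, and camera gave the higher direction with an unadjusted p of 0.075.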

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

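The test on placental genes not looked at before was set before its result was seen, and the other test in this part was chosen after. Placental genes fall mostly below the level filter and so outside the comparisons, yet were bright on 1 array. Of 46 genes of the placental list on the array, 35 lay below the filter. Of these 35, 30 were highest on the labelled knockout replicate 2 array and 28 were over 4-fold above every other array. The median log2 excess of the 35 over the highest other array was 5.592. Of these 35, 25 were chosen because they were high on that array, and all 25 were over 4-fold above the others, with a median of 6.95. Of the 10 not looked at before, 5 were highest there and 3 over 4-fold above the others, with a median of 0.31. Prl8a9, a placental prolactin, read 3.44 and 4.27 in wild type, 4.43 in labelled knockout replicate 1 and 29880 in labelled knockout replicate 2. Tpbpb and Ceacam11, both trophoblast genes, reached 38677 and 43794 on that array.

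Labelled knockout replicate 1 did not share this signal, which, as far as 1 library can show, argues against an effect common to both labelled knockout samples. There the 46 genes of the placental list lay at a median log2 difference of -0.3566 from the wild-type mean, with a bootstrap interval from -0.50 to -0.21. That interval resamples genes, at a median signal of 46.4 there, and gives no spread between samples. Of the 46, 31 were chosen because they were high on labelled knockout replicate 2. The 15 not looked at before had a median of -0.45. A candidate explanation is placental tissue in the replicate 2 sample. In the 15 genes of the placental list not looked at before, the median log2 excess was 0.5423. On that array 10 of 15 were highest and 3 were over 4-fold above every other array. That median lies between the bounds of above 1 and at most 0.3 set in advance, so that test left the explanation open. It is a weak test, since some of those 15 genes were not particular to placenta here. Peg10, Sin3b and Tfpi were above the filter on all arrays, where added placental RNA would be hard to see. The largest excesses were 2.96 for Prl7c1, 2.50 for Prl8a2 and 2.38 for Rhox6. The lowest were -1.62 for Hsd11b2 and -1.58 for Cyp11a1. Placental tissue taken along at dissection, RNA or cDNA carried over at a later step and a change in that one sample cannot be told apart here.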

How the results depend on the processing

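All alternatives were chosen before the data were examined except the block with quantile normalisation and the block with an estimated correlation. The count of genes was 0 in every setting with all 4 arrays and ranged from 0 to 492 when 1 array was left out, where the lone array is assumed to vary like the other group. It was 0 and 1 without wild-type replicates 1 and 2, 492 (184 higher, 308 lower) without labelled knockout replicate 1 and 104 (91 higher, 13 lower) without labelled knockout replicate 2, and a fit with 3 arrays has 1 residual degree of freedom. The Cacna1h difference kept its sign and did not pass in any setting, from 0.11 to 0.74 with 1 array left out, and gave no value at the 75th percentile filter, which removes the gene. The 10 lists became 7 to 15 with all 4 arrays and the preset correlation, from 10 to 18 with 1 array left out, and 0 with an estimated correlation, with or without the block. The cartilage median stayed at -0.18 with an estimated correlation, alone (adjusted p = 0.839) or with the block (0.795), and ranged from -0.34 to 0.023 with 1 array left out. Its adjusted p with the preset correlation was at most 0.0051 with all 4 arrays and 0.776 without labelled knockout replicate 1. Genes beside Cacna1h at an unadjusted p under 0.05 made up 4% to 6%.

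Of 553 list values under alternatives, 58 had a median of the other sign, 23 with all 4 arrays and 35 with 1 left out. By the direction of the camera test 5 turned, each with 1 array left out. These were adipocytes without wild-type replicate 1, cardiac muscle and squamous epithelium without labelled knockout replicate 1, and calcium stores and pumps and ribosomal proteins without labelled knockout replicate 2. With 1 array left out these medians ranged from -0.48 to 0.50 for adipocytes, -1.54 to 1.55 for cardiac muscle, -0.42 to 0.69 for squamous epithelium, -0.30 to 0.20 for calcium stores and pumps and -0.24 to 0.44 for ribosomal proteins. The cause was not tested. Of 2400 named gene values under alternatives, 75 passed the threshold, all with a labelled knockout array left out, and 43 had the other sign without passing. The filter leaves out genes whose mean level over the 4 arrays lay below a signal of 397, so differences in such dim genes were not tested in the main fit.

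With the replicate number as a block, 0 genes passed (smallest adjusted p 0.158, with 1359 at an unadjusted p under 0.05), 15 lists passed (7 higher, 8 lower) and the Cacna1h difference was 0.43. These were the 10 above and airway smooth muscle (adjusted p = 0.039), fibroblasts and perichondrium (0.011), ribosomal proteins (0.010), glycolysis and hypoxia (0.039) and skeletal muscle (0.022). With an estimated correlation as well, the adjusted p of these 5 was 0.914 for smooth muscle and 0.795 for the others. With quantile normalisation as well, 0 genes and 14 lists passed. The labels do not say that the numbers mark a pair or batch. Across genes, differences of replicate 2 from replicate 1 correlated between genotypes with r = 0.3197, and genes are not independent replicates.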

Other observations

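The tests in this part were chosen after the results they bear on were seen. Wild-type replicate 2 held transcripts of several other organs. Afp, the fetal serum protein of liver and yolk sac, read 24975 there and 110 in wild-type replicate 1, and Apoa1, an apolipoprotein, read 11262 and 197. Flg, the filaggrin gene of the epidermis, read 4001 there and 15.7 in wild-type replicate 1. Of the liver and yolk sac list, 10 of 11 genes chosen after their values were seen were highest in wild-type replicate 2, by a median log2 excess of 3.11 over the next array. Of the 15 not looked at before, 11 were highest there, by a median of 0.17. Of the skin and hair list these were 9 of 9, by 4.34, and 12 of 17, by 0.12. Some of those 17, namely Krt1, Krt10, Lor and Dsg1a, also belong to the squamous epithelium list tested earlier. Ucp1, the uncoupling protein of brown fat, read 4434 in wild-type replicate 2 and at most 219 elsewhere. Salivary gland genes were highest in wild-type replicate 2 in 12 of 18 cases, 5 of them among the 8 not looked at before, and Smgc, a submandibular gland protein, read 3.74, 28112, 12724 and 4139 on wild-type arrays 1 and 2 and labelled knockout arrays 1 and 2. In wild-type replicate 1, 8 of the 18 salivary genes, 2 of the 26 liver genes and 3 of the 26 skin genes were above the filter level. In the same order these counts were 16, 15 and 18 in wild-type replicate 2. They were 12, 3 and 3 in labelled knockout replicate 1 and 13, 8 and 8 in labelled knockout replicate 2, so such signals were not particular to wild-type replicate 2. The source of those signals is not known.

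Labelled knockout replicate 2 differed from the other arrays in further genes. The hypertrophic cartilage and bone list did not pass between the genotypes, and 9 of its 12 genes on the array were highest there. Named after their values were seen are Ibsp, bone sialoprotein, at 5780 against 126, 123 and 175, and Panx3, a channel of osteoblasts and hypertrophic chondrocytes, at 1394 against 49.2, 85.7 and 42.6. Ttr, transthyretin, read 27074 there and 167, 4684 and 556 elsewhere. Of 15 cardiac genes on the array, 9 were dimmest there and 5 in wild-type replicate 2, and 14 were brightest in labelled knockout replicate 1. Nppa, atrial natriuretic peptide, read 131 on labelled knockout replicate 2 and 7728, 2974 and 15926 elsewhere. Pth, parathyroid hormone, was bright on all arrays, at 18889 ± 4700 in wild type and 16771 ± 4027 in the labelled knockout (SD, n = 2). Within the replicate numbers, the cardiac list lay at the 100th percentile of 10000 random lists of matched level for replicate 1 and at 0 for replicate 2, as a description of these arrays.

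Thymus genes were higher in the labelled knockout mainly between the replicate 1 arrays. The T-cell list differed by a median log2 value of 1.405 between the wild-type arrays, at least as much as between the genotypes, and by -0.1371 between the replicate 2 arrays. The thymic epithelium list, added later, was higher in 15 of 17 genes between the replicate 1 arrays, with a median of 1.89, and in 14 of 17 between the replicate 2 arrays, with a median of 0.26. The genotype median of that list was 0.94, and its wild-type arrays differed by 0.47. Of these 17 genes, 4 were chosen after their values were seen, among them Psmb11, Prss16 and Ccl25. The 13 not looked at before were higher in 11 genes between the replicate 1 arrays (median 1.85) and in 10 between the replicate 2 arrays (0.18). Their genotype median was 0.79, and the wild-type arrays differed by 0.46 in them. Thymus tissue carried along in differing amounts and an effect of genotype cannot be told apart here, since the lists differ in what the wild-type arrays and the replicate 2 arrays show. Dissections with separate thymus would be needed.

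The cartilage matrix list was lower in the labelled knockout between the replicate 1 arrays. Dilution of the trachea by other tissue could lower cartilage genes, and an even one would lower other tracheal genes alike. The replicate 1 medians were -0.36 for cartilage, -0.11 for basal epithelium, -0.23 for multiciliated cells, -0.05 for secretory cells, -0.11 for fibroblasts and 0.19 for smooth muscle. In two-sided permutation tests over genes, treated as independent, cartilage was lower than the basal (p = 0.0036), secretory (0.0012), fibroblast (0.00076) and smooth muscle lists (1e-05, the smallest that 100000 resamples can give), but not past 0.05 for multiciliated cells (0.05734). These values compare 1 library with 1 library, and other tissue can bring muscle or epithelium of its own, so dilution stays open. So do a smaller cartilage part in that sample, an effect of genotype and an uneven dissection. The 4 arrays make 3 splits into equal groups, too few for a share under 0.05. Of these 3, 2 gave as small a p for the list, with 4.04e-05 for the genotype and 1.4e-07 for wild-type replicate 2 with labelled knockout replicate 1 against the rest.

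The number of lists passing with the preset correlation has the same limit. With 3 splits no share under 0.05 can be had, the genotype gave 10 lists, and 2 of the 3 splits gave as many, the highest other being 15 for the split by replicate number. That split also gave 7 genes past the threshold and 1520 at an unadjusted p under 0.05, against 0 and 536 for the genotype, which points to a structure by replicate number in part of the genes. Correlations over all 11694 genes did not follow the number throughout. They were r = 0.964 for the replicate 1 arrays, 0.957 for the wild-type arrays, 0.952 for wild-type replicate 2 with labelled knockout replicate 1 and 0.947 for the replicate 2 arrays. The lowest were 0.936 for the labelled knockout arrays and 0.930 for wild-type replicate 1 with labelled knockout replicate 2. The labelled knockout arrays were thus less alike than the arrays of either replicate number. The remaining split gave 9 lists, 0 genes and 159 at an unadjusted p under 0.05.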
